A study of Mus musculus with 9 samples.

How the data were processed

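RNA from mouse embryonic stem (ES) cells was measured on 9 Illumina beadchip arrays of 1 colour each. Per the labels, 5 arrays carried RNA of an ES line that expresses the reverse tetracycline transactivator (Aniv15): 2 arrays of a luciferase control with doxycycline and 3 of a rescue clone named Wdr5R4 without doxycycline, described as a Wdr5 knockdown by short hairpin RNA (shRNA). The other 4 arrays carried RNA of CCE or E14T cells, and the labels do not say which line was used for which sample: 2 arrays of cells with an shRNA against Oct4 (gene symbol Pou5f1) and 2 with an shRNA against GFP. The shared growth text lists doxycycline for every sample. The absence of doxycycline in the Wdr5 knockdown therefore rests on the group label, the sample titles and the column headers, against that text. All cells were grown on mouse embryonic fibroblast feeders with LIF, and RNA was extracted with Trizol, purified with DNase I treatment, checked on a Bioanalyser and amplified to biotinylated cRNA.

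The authors deposited probe intensity values that had not been normalized between arrays, per the file headers and the values, which lie on a linear scale and fall below 0 for dim probes, as after a background subtraction. Beside each intensity the authors deposited a detection score, a fraction between 0 and 1 that is near 1 for bright probes. The authors also deposited normalized log2 values for each array and, per the file headers, a table of log2 fold changes with p-values for each comparison. Limma is named in the submitters' processing notes with no role or version, and the normalization method, scanner software and version are not given in the sources used here. The deposited log2 values keep the rank order of the intensities within each Oct4 and GFP array and have a floor, at 7.6 in the Wdr5 set and 7.47 in the Oct4 set. Their base was inferred from the values, and their array medians were 7.78 on each array of the Wdr5 set and 7.62, 7.64, 7.62 and 7.63 in the Oct4 set. The probe identifiers of the deposited log2 values of the Wdr5 set could not be matched to gene names, so that table was used only for counts of probes.

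Intensities were processed in R 4.3.3 with limma 3.58.1. The neqc function corrected the background with a normal-exponential model based on the detection scores, added an offset of 16, normalized the arrays of each comparison by quantiles and took log2. A probe was kept with a detection score above 0.95 on at least 2 arrays of the comparison, which left 13529 of 25697 probes in the Wdr5 set and 11324 of 46643 in the Oct4 set. Each gene was represented by its kept probe of highest mean signal, giving 10119 and 9276 genes. Quantile normalization gives every array the same distribution, so it removes any change in the total amount of messenger RNA and makes each fold change relative to the other genes. The offset pulls the fold changes of dim probes towards 0.

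Gene symbols came from the accessions in the tables, matched to a RefSeq gene table of assembly GRCm38.p6 used for names only. This named 24202 probes of the Wdr5 set and 25596 of the Oct4 set. A further 1495 and 21034 kept the symbol of the table, updated through a unique synonym for 301 and 4104 of them. Spreadsheet software had damaged the symbols of 45 probes of the Oct4 set, of which 32 were recovered and 13 stayed unnamed.

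The comparisons were the Wdr5 knockdown against the luciferase control and the Oct4 knockdown against the GFP control. They used separate platforms and cell lines, shared no control arrays and were fitted separately with lmFit and eBayes, with group as the only term. Tests were two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05 on the adjusted p. Where a gene was not above background on any array of a group, only a bound on its fold is given. The exception is the fitted differences between the knockdowns, whose sizes are not read. The bound sets the mean of the brighter group against the mean, per array of the dimmer group, of the higher of the lowest signal among detected probes and the gene's own signal. A called gene whose bound would be under 1 is counted as called and given no fold. A gene below background in a group could pass the filter only through the other group, so its direction adds no support to a list. The bounds hold only for the background correction, offset and normalization used here.

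In total 17 gene lists with 507 symbols were fixed before the data were examined: pluripotency, COMPASS and Wdr5 complexes, trophectoderm, primitive endoderm, mesoderm and primitive streak, ectoderm and neural, Hox genes, feeder fibroblast, p53 targets, cell cycle, nucleolus and ribosome biogenesis, integrated stress response, interferon response, two-cell-like state, germline, Nodal and Wnt targets, and glycolysis and hypoxia. Lists with at least 5 measured members were tested against all other genes with camera at a preset correlation of 0.01 and again with an estimated correlation. In the second form camera has only the residual degrees of freedom of the fit, 3 in the Wdr5 and 2 in the Oct4 set. It then has little power, so a list left uncalled there is not evidence that the list did not change. Fry was run beside camera and tests whether the genes of a list move, on balance, one way, without comparing them with other genes. The rule for named genes was also fixed before the data were examined. It takes the shRNA target, the factors Pou5f1, Sox2, Nanog, Klf4, Esrrb and Zfp42, and the Wdr5 partners Ash2l, Rbbp5 and Dpy30. It adds the 10 genes with the largest positive and the 10 with the largest negative called change whose groups do not overlap, and up to 4 called members of each list with the largest change. Some results that the rule takes are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

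The number of arrays limits the precision. The median standard error of a log2 fold change was 0.09 in the Wdr5 set and 0.17 in the Oct4 set. The procedure was tested on simulated data made from these arrays. For the Wdr5 set (10119 genes) it recovered 59.7%, 98.5% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale, and 6.52% of its calls were false. For the Oct4 set (9276 genes) it recovered 5.97%, 88.1% and 100%, and 4.44% of its calls were false. In the real sets many more genes were called, 68.7% in the Wdr5 and 42.4% in the Oct4 set, so these shares need not hold there. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

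Alternatives were no background correction, a background model without detection scores (offset 50), scaling to a common median, the authors' normalized values, other filters on dim probes, all probes of a gene, a 2-fold minimum, other variance models, array weights, the replicate number as a block, and leaving out each array. Probes detected on every array, scaling over kept probes and a crossed pairing of the Oct4 and GFP arrays were added after seeing the data. So was a test in which a loess trend of the fold change on mean signal was subtracted from the Oct4 knockdown arrays before the fit. The beadchip was not used as a block because the columns do not give it. Plots were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.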

Results

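The arrays measured gene expression in mouse ES cells after knockdown of Wdr5, a WD-repeat subunit shared by the COMPASS family of histone H3 lysine 4 methyltransferases, and of Oct4 (Pou5f1), a transcription factor required for pluripotency. The title of the series places the work in the question of how Wdr5 relates to self-renewal and the transcription factor network of ES cells. The Wdr5 comparison set 3 arrays of the knockdown against 2 of the luciferase control, and the Oct4 comparison set 2 arrays of the knockdown against 2 of the GFP control. Mean deposited intensities were 448 and 519 on the luciferase arrays and 429, 400 and 375 on the Wdr5 knockdown arrays. The GFP arrays had means of 344 and 278, and the Oct4 knockdown arrays were dimmer, at 110 and 111. Between 12156 and 13104 of the 25697 probes were detected per array in the Wdr5 set, and between 9020 and 11804 of the 46643 probes in the Oct4 set. Normalized values correlated across the tested genes, each by its brightest kept probe, at 0.995 to 0.996 within the groups of the Wdr5 set. Between these groups the correlation was 0.926 to 0.929. In the Oct4 set the correlation was 0.978 between the GFP arrays, 0.989 between the Oct4 knockdown arrays and 0.867 to 0.891 between groups.

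The target of each shRNA was lower in every knockdown array than in every control array. The Wdr5 probe read 988 and 1097 on the luciferase arrays and 464, 459 and 427 on the knockdown arrays before normalization. After it, the mean log2 signal was 9.93 ± 0.05 (SD, n = 2) in the control and 8.97 ± 0.06 (SD, n = 3) in the knockdown. Wdr5 thus fell 1.94-fold (log2 fold change -0.96 ± 0.07 SE, limma adjusted p = 0.000121). The brighter Pou5f1 probe read 4609 and 4137 on the GFP arrays and 297 and 305 on the Oct4 knockdown arrays. Its mean log2 signal went from 11.52 ± 0.11 (SD, n = 2) to 9.24 ± 0.05 (SD, n = 2), a 4.85-fold fall (log2 fold change -2.28 ± 0.15 SE, limma adjusted p = 0.000685). Each target was also lower in the other knockdown. Pou5f1 changed by -0.96 ± 0.18 on the log2 scale in the Wdr5 knockdown (adjusted p = 0.00448), where its dimmer probe changed by -2.03, and Wdr5 changed by -0.81 ± 0.15 in the Oct4 knockdown (limma adjusted p = 0.0108), a gene and comparison chosen after the value was seen. That last call ended without Oct4 knockdown replicate 1 (-0.79, limma adjusted p = 0.121) or replicate 2 (-0.85, limma adjusted p = 0.0838), and the value ranged from -1.42 under scaling to a common median to -0.49 in the authors' deposited table.

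**Figure D1:**
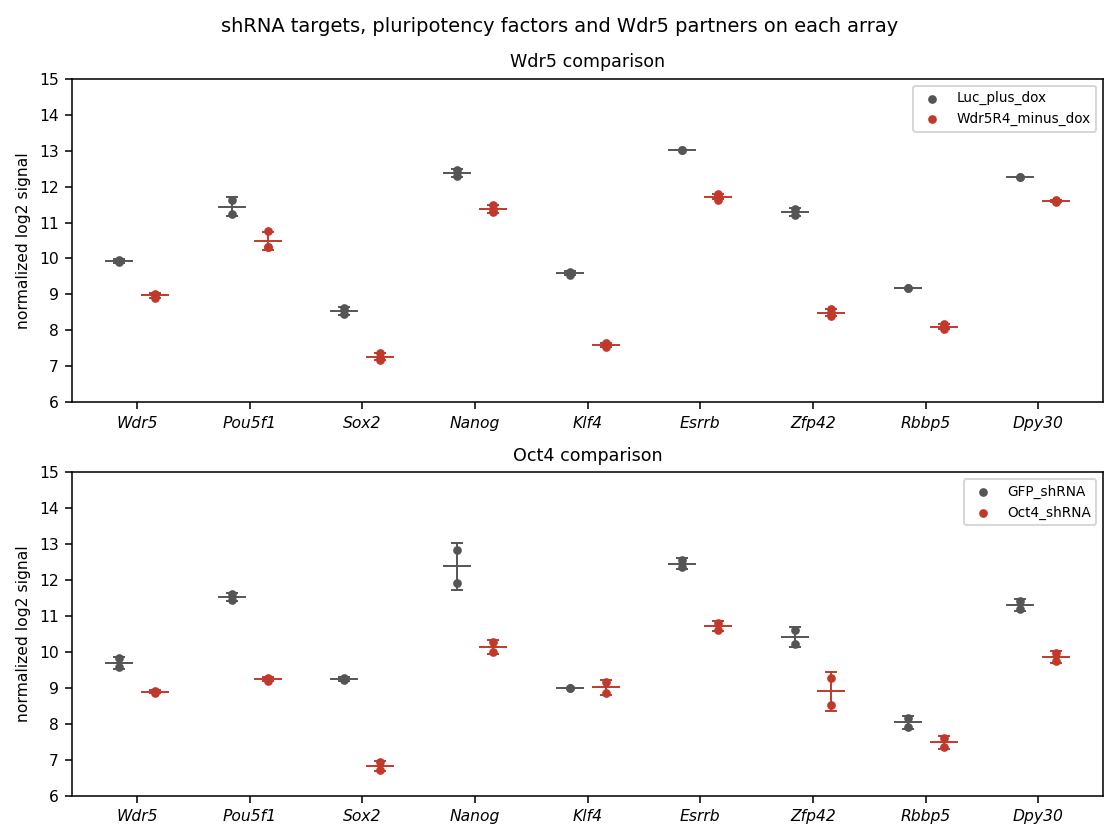
Normalized log2 signal on the vertical axis of Wdr5, pluripotency factor genes and the Wdr5 partner genes Rbbp5 and Dpy30, with 1 point per array, a long line at the group mean and bars of 1 SD, control in grey and knockdown in red. Every knockdown array lies below every control array for both shRNA targets, with Wdr5 at 9.93 against 8.97 in the Wdr5 comparison and Pou5f1 at 11.52 against 9.24 in the Oct4 comparison.

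Wdr5 knockdown cells had lower levels of pluripotency factors and higher levels of fibroblast marker genes than the luciferase control by camera with a preset correlation. With an estimated correlation neither list was called (adjusted p = 0.17 and adjusted p = 0.148). Zfp42 (Rex1), a zinc finger marker of naive ES cells, changed by -2.80 ± 0.09 on the log2 scale (SE, 2 against 3 arrays). Among the genes with the largest rise were Lox, the enzyme that crosslinks collagen, which was at least 29.4-fold higher, Cav1, the coat protein of caveolae (23.1-fold), and Edn1, the vasoconstrictor peptide endothelin 1 (16.2-fold). Calb2, which encodes the calcium-binding protein calretinin, fell 24.5-fold, the X-linked Xlr4a 17.9-fold and Pfkp, the platelet form of the glycolytic enzyme phosphofructokinase, 15.4-fold. Dimmer second probes gave smaller falls, with a log2 fold change of -3.12 against -4.61 for Calb2 and -2.59 against -3.94 for Pfkp. Sizes were also smaller in the authors' deposited table, at -2.20 for Calb2, -2.65 for Xlr4a and -2.33 for Pfkp on the log2 scale. There Lox was at 2.11, Cav1 at 2.49 and Edn1 at 2.20.

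Of the 10119 genes tested, 3861 were higher and 3086 lower in the Wdr5 knockdown at a limma adjusted p under 0.05. With a change of at least 2-fold, 1141 were higher and 974 lower. The median absolute log2 fold change was 0.51, and 420 genes were above background in the knockdown only and 337 in the control only. The other genes of the largest rises were Ccn4, a matricellular Wnt target (15.5-fold), Tnc, encoding tenascin C (13.8-fold), the cardiac actin gene Actc1 (13.0-fold), Serpinf1 (12.7-fold), the smooth muscle actin gene Actg2 (at least 10.6-fold), Inhba, the activin subunit (at least 10.4-fold), and the keratin gene Krt14 (at least 9.76-fold). Further large falls were those of Gstp2 (13.1-fold), the translation elongation factor gene Eef2 (9.51-fold, with all 3 of its probes lower), Slc25a36 (8.80-fold), Ly6g6e (7.99-fold) and the kallikrein genes Klk1 (at least 9.49-fold) and Klk1b27 (at least 5.65-fold). Pygl, the liver glycogen phosphorylase, fell 7.53-fold and was above background on 1 of the 3 knockdown arrays. In the authors' deposited table Actg2 was at 1.17, Inhba at 1.15 and Krt14 at 1.08 on the log2 scale, under the bounds given here. Klk1, at -1.05, and Klk1b27, at -0.74, also fell by less than their bounds there. The same held for Dcn (1.00) and Rhox6 (-0.71), whose bounds are given below.

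Of the 36 measured pluripotency genes, 24 fell, 6 rose and 6 were not called, with the same counts of 24 and 6 adjusted over the list alone. The median log2 fold change was -0.82 and the camera adjusted p was 0.000172, against an adjusted p = 0.17 with an estimated correlation. After Zfp42, the largest falls were those of Dppa3 (log2 -2.45 ± 0.10), Fbxo15 (-1.65 ± 0.07) and Klf4, a reprogramming factor gene, which fell 3.99-fold. Esrrb changed by -1.31 ± 0.08, Sox2 by -1.27 ± 0.09 and Nanog by -1.01 ± 0.09, each below the adjusted p of 0.00448 that Pou5f1 had. Among 17 COMPASS and Wdr5 complex genes, 8 rose and 4 fell, also adjusted over the list alone, with a median of 0.14 and a camera adjusted p of 0.447. The core subunit genes Rbbp5 (log2 -1.08 ± 0.07) and Dpy30 (-0.67 ± 0.07) fell, and the methyltransferase genes Setd1b (1.42 ± 0.08) and Kmt2b (0.88 ± 0.07) and the demethylase gene Kdm6a (0.74 ± 0.07) rose. Ash2l was at -0.28 ± 0.07 (adjusted p = 0.0112), while its dim second probe was at 0.78, and its call ended under either median scaling, with the replicate block and without luciferase replicate 1.

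Fibroblast markers were the list with the lowest camera adjusted p in the Wdr5 comparison. Of 28 measured, 25 rose and 1 fell, also adjusted over the list alone, with a median log2 fold change of 1.85 and a camera adjusted p of 2.8e-07, against an adjusted p = 0.148 with an estimated correlation. The list holds Lox, Cav1 and Serpinf1, named above, and the matrix proteoglycan gene Dcn, which was at least 8.87-fold higher. Of the markers, 23 were above background on every control array and none belonged to another list. The gene that fell was Thy1 (log2 -0.44 ± 0.09), and Lgals1 (-0.02 ± 0.08) and Mmp2 (-0.16 ± 0.08) were not called. Those 3 were chosen after their values were seen.

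Of the lineage lists, measured on the same arrays as these fibroblast markers, only mesoderm and primitive streak was called by camera. In that list 11 of 17 genes rose and 3 fell, also adjusted over the list alone (median 0.64, camera adjusted p = 0.0434, and adjusted p = 0.186 with an estimated correlation). The transcription factor gene Mixl1 (log2 1.80 ± 0.11) and the signalling genes Bmp4 (1.98 ± 0.07) and Wnt3 (1.77 ± 0.09) rose. That list call ended with the replicate block (camera adjusted p = 0.0677), under 2 alternatives added after seeing the data, and without luciferase replicate 2 (adjusted p = 0.0732) or Wdr5 knockdown replicate 1 (adjusted p = 0.0644). Of 19 primitive endoderm genes, 11 rose and 5 fell (12 and 5 adjusted over the list alone), with a median of 0.47, or 0.30 with genes below background at their bound, and a camera adjusted p of 0.19. The basement membrane collagen genes Col4a1 (3.46 ± 0.08) and Col4a2 (2.76 ± 0.07), Foxq1 (2.52 ± 0.09) and Dab2 (1.96 ± 0.09) rose. Of 15 ectoderm and neural genes, 9 rose and 2 fell, also adjusted over the list alone (median 0.43, camera adjusted p = 0.147). The intermediate filament gene Nes (3.21 ± 0.17), Fgf5, a marker of primed epiblast (2.65 ± 0.11), and Meis2 (2.20 ± 0.07) rose, and the retinoid-binding protein gene Crabp1 fell (-2.60 ± 0.10) and was above background on 1 of the 3 knockdown arrays. Of 21 Hox genes, 12 rose and 3 fell, also adjusted over the list alone (median 0.45, camera adjusted p = 0.134), among them Hoxd10 (1.77 ± 0.07), Hoxb4 (1.71 ± 0.18, above background on 1 of the 2 control arrays) and Hoxd3 (1.36 ± 0.09), while Hoxb7 was at least 2.32-fold lower. The trophectoderm list was split, with 7 genes higher and 11 lower of 25, also adjusted over the list alone (median -0.18, camera adjusted p = 0.236). Tfap2a rose (2.43 ± 0.12), and the homeobox genes Rhox6 (at least 5.80-fold) and Rhox9 (-1.87 ± 0.08) and the placental gene Plac1 (-1.57 ± 0.16, above background on 2 of the 3 knockdown arrays) fell.

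The lists of glycolysis, stress response, cell cycle and germline genes lay below the other genes in the Wdr5 knockdown. In the glycolysis and hypoxia list 15 of 21 genes fell and 4 rose, also adjusted over the list alone, with a median of -0.71, or -0.64 with bounds (camera adjusted p = 0.00253, and adjusted p = 0.17 with an estimated correlation). Besides Pfkp, the aldolase gene Aldoc (-2.77 ± 0.09), the pyruvate dehydrogenase kinase gene Pdk1 (-2.12 ± 0.12) and Ndrg1 (-1.52 ± 0.07) fell. In the integrated stress response list 15 of 24 genes fell and 4 rose (16 and 4 adjusted over the list alone), with a median of -0.47 and the same camera adjusted p of 0.00253 (adjusted p = 0.17 with an estimated correlation). The members with the largest falls were the serine synthesis genes Phgdh (-2.76 ± 0.08) and Psat1 (-2.10 ± 0.08), followed by Trib3 (-1.28 ± 0.13), while the stress transcription factor gene Atf3 rose (1.75 ± 0.09). Among 32 cell cycle genes 17 fell and 6 rose (18 and 6 adjusted over the list alone), with a median of -0.28 (camera adjusted p = 0.0178, and adjusted p = 0.17 with an estimated correlation). The replication helicase gene Mcm6 fell (-2.23 ± 0.09), and Ccnd2, encoding cyclin D2 (3.32 ± 0.07), and the kinase inhibitor genes Cdkn2a (2.27 ± 0.16) and Cdkn2b (2.13 ± 0.12) rose. Under scaling to a common median the adjusted p of that list was 0.0535, and under scaling over kept probes, added after seeing the data, it was 0.0509. Of 14 germline genes 10 fell and 2 rose, also adjusted over the list alone, with a median of -0.87, or -0.37 with bounds (camera adjusted p = 0.0184, and adjusted p = 0.17 with an estimated correlation). The meiotic cohesin gene Smc1b was at least 2.68-fold lower, and the piRNA pathway genes Mov10l1 (-1.69 ± 0.18) and Piwil2 (-1.56 ± 0.25) and the RNA-binding protein gene Dazl (-1.40 ± 0.08) fell. Of the 3 knockdown arrays, Mov10l1 was above background on 1 and Piwil2 and Dazl each on 2. The germline call ended without luciferase replicate 1 (camera adjusted p = 0.139) or replicate 2 (adjusted p = 0.143).

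Lists without a call by camera also had members that changed. Of 28 p53 targets 15 rose and 6 fell, also adjusted over the list alone (median 0.34, camera adjusted p = 0.19), with Plk2 (2.29 ± 0.08), the p53 ubiquitin ligase gene Mdm2 (1.97 ± 0.07) and Fbxw7 (1.62 ± 0.10) higher and the secreted factor gene Gdf15 lower (-1.89 ± 0.09, above background on 2 of the 3 knockdown arrays). Of 20 nucleolus and ribosome biogenesis genes 13 rose and 3 fell (14 and 3 adjusted over the list alone), with a median of 0.56, or 0.54 with bounds, and a camera adjusted p of 0.051. Pes1 rose (2.02 ± 0.07), and Nip7 (-1.63 ± 0.10), Nop56 (-1.27 ± 0.12) and Nhp2 (-1.17 ± 0.06) fell, although the dim second probe of Nhp2 was at 0.50. Of 16 Nodal and Wnt targets 6 rose and 5 fell, also adjusted over the list alone (median 0.21, camera adjusted p = 0.491), with the Wnt feedback genes Sp5 (1.69 ± 0.11), Axin2 (1.52 ± 0.07) and Notum (1.15 ± 0.15) and the Nodal antagonist gene Lefty1 (1.06 ± 0.08) higher. Of 19 interferon response genes 9 rose and 7 fell, also adjusted over the list alone (median 0.12, camera adjusted p = 0.785). The chemokine gene Cxcl10 was at least 2.52-fold higher and Ifitm3 rose (1.29 ± 0.08), while Usp18 (-1.35 ± 0.07) and Bst2 (-1.27 ± 0.23) fell. Of 3 measured two-cell-like genes 1 was called, Gm428, which was at least 1.02-fold higher and whose call ended with a trended variance model, with the replicate block and without either luciferase array. It was above background on 2 of the 3 knockdown arrays, and without Wdr5 knockdown replicate 2 or 3 no two-cell-like gene was called. Some counts of falling members moved by over 1.5 times with 1 array left out. Genes detected only on the 2 luciferase arrays dropped out by construction when 1 of these was removed. In the germline list 5 of 14 genes were not above background in 1 of the groups. Without either luciferase array 7 trophectoderm, 1 Hox and 5 germline genes were lower, and Nodal and Wnt targets lower were 3 without replicate 1 and 2 without replicate 2. Interferon response genes lower were 4 without luciferase replicate 1, mesoderm genes lower 1 without luciferase replicate 2, and Nodal and Wnt targets lower 3 without Wdr5 knockdown replicate 2. Under scaling to a common median 4 ectoderm genes and 3 Nodal and Wnt targets were lower and 2 glycolysis genes higher. Clone, shRNA and doxycycline differ together between the groups, so none of these changes can be assigned to Wdr5 apart from the other differences. Of the 2505 genes with several kept probes, 357 had probes called in opposite directions. Other probes of genes named above were at 1.79 on the log2 scale for Actc1, 3.50 and 0.94 for Tnc, -1.06 for Pygl, -0.24 for Rbbp5, 1.79 for Nes, 1.10 for Tfap2a, -0.85 for Ndrg1, 1.19 for Cdkn2a, 0.45 for Fbxw7, 1.24 and -0.17 for Mdm2, and -2.87, -0.71 and -1.41 for Mcm6.

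Oct4 knockdown cells had lower levels of pluripotency genes and higher levels of trophectoderm, primitive endoderm and fibroblast marker genes than the GFP control by camera with a preset correlation. With an estimated correlation none of these 4 lists was called (adjusted p = 0.411 for each). Acta2, encoding smooth muscle actin, rose 193-fold (log2 7.59 ± 0.35 SE, n = 2 arrays per group) by its brightest probe, while its other probes were at 5.69 and 4.81. The simple keratin genes Krt18 (85.5-fold) and Krt7 (74.3-fold), each above background on 1 of the 2 control arrays, and Krt8 (37.4-fold) also rose. Sox2, the partner of Oct4 on many enhancers, changed by -2.42 ± 0.15 on the log2 scale. Eras, an ES cell Ras gene, fell 9.91-fold and was above background on 1 of the 2 knockdown arrays, and Ezh2, the Polycomb methyltransferase, fell 9.47-fold.

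Of the 9276 genes tested, 2250 were higher and 1680 lower in the Oct4 knockdown, so that 57.3% of the calls were higher. This split depended on the processing. Scaling to a common median gave 578 higher and 2765 lower (17.3% higher) and moved the median log2 fold change of all genes from -0.02 to -0.53, because the median over all probes there lies in the background. Scaling over kept probes only, chosen after seeing the data, gave 2103 and 1768 (54.3%), and probes detected on every array, likewise, gave 1279 and 1511 (45.8%). Without Oct4 knockdown replicate 1 the counts were 387 higher and 418 lower, and without replicate 2 they were 580 and 692. With a change of at least 2-fold, 1131 genes were higher and 682 lower. In this set 940 genes were above background in the knockdown only and 267 in the control only.

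The other genes of the largest rises were the skeletal actin gene Acta1 (at least 66.4-fold), Tpm2, encoding a tropomyosin (31.8-fold, above background on 1 of the 2 control arrays), the imprinted growth factor gene Igf2 (30.2-fold), the neurotensin gene Nts (at least 20.3-fold), Gadd45g (at least 18.5-fold) and the myelin protein gene Pmp22 (at least 15.96-fold). Further large falls were those of the gene named Tera-pending in the table (at least 9.62-fold), Robo4 (9.18-fold, above background on 1 of the 2 knockdown arrays), Socs2 (8.97-fold), Mreg (7.35-fold), Cobl (6.52-fold), Yme1l1 (at least 5.14-fold), Bdh2 (at least 5.00-fold) and Otx2, a homeobox gene of the epiblast and forebrain (at least 3.50-fold).

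In the pluripotency list 24 of 31 genes fell and none rose (25 and 0 adjusted over the list alone), with a median of -1.55 and a camera adjusted p of 4.9e-10, against an adjusted p = 0.411 with an estimated correlation. Gdf3 (-2.60 ± 0.16), Fbxo15 (-2.57 ± 0.20), Nanog (-2.24 ± 0.32), Esrrb (-1.75 ± 0.16) and Zfp42 (-1.52 ± 0.30) fell. The other Nanog probes were at -4.99 and -4.29, and a dim Esrrb probe was at 0.78. Klf4 was not called by its brightest probe (0.02 ± 0.16, adjusted p = 0.926), while its other probes were at -1.28, which was called, and -0.34. Of 22 COMPASS and Wdr5 complex genes 6 fell and 3 rose (7 and 4 adjusted over the list alone), with a median of -0.20 (camera adjusted p = 0.204). Dpy30 (-1.45 ± 0.17), Kansl2 (-0.98 ± 0.21), Ash2l (-0.76 ± 0.22) and Rbbp5 (-0.56 ± 0.17, adjusted p = 0.0495) fell, Rbbp5 losing its call in several alternatives, the replicate block among them, Wdr82 was at least 1.71-fold lower and Ncoa6 at least 1.74-fold higher.

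Trophectoderm, primitive endoderm and mesoderm genes were called higher as lists, and fibroblast markers rose on the same arrays. Not above background in 1 of the groups were 7 of 20 trophectoderm, 1 of 17 primitive endoderm, 3 of 5 mesoderm and 7 of 19 fibroblast genes. Those below background in the GFP control could pass the filter only through the knockdown arrays. Their direction adds no support, although they are among the counts and the set tests. Among 20 trophectoderm genes 15 rose and 1 fell, also adjusted over the list alone, with a median of 1.44, or 0.90 with bounds (camera adjusted p = 6e-05, and adjusted p = 0.411 with an estimated correlation). Rhox9 was at least 9.30-fold higher, beside the keratins named above. Among 17 primitive endoderm genes 13 rose and 1 fell, also adjusted over the list alone, with a median of 1.55 (camera adjusted p = 0.000181, and adjusted p = 0.411 with an estimated correlation). The basement membrane gene Nid1 rose 15.4-fold, Col4a1 by 2.54 ± 0.15, the collagen chaperone gene Serpinh1 by 2.47 ± 0.18 and Foxq1 by 2.15 ± 0.18 on the log2 scale, Foxq1 being above background on 1 of the 2 control arrays. Among 19 fibroblast markers 13 rose and none fell (14 and 0 adjusted over the list alone), with a median of 2.30, or 1 with bounds (camera adjusted p = 3.7e-06, and adjusted p = 0.411 with an estimated correlation). They include Acta2, Lgals1 (24.3-fold), Timp3 (at least 17.2-fold) and Tagln (at least 7.69-fold), and 9 of the 19 were above background on every control array. In the mesoderm and primitive streak list 4 of 5 genes rose, also adjusted over the list alone (median 1.16, or 0.37 with bounds, camera adjusted p = 0.0357, and adjusted p = 0.492 with an estimated correlation). Among them were Msx2 (at least 1.42-fold), Rspo3 (at least 1.26-fold) and Bmp4 (0.68 ± 0.15), whose dimmer probe was at -1.08. Without GFP replicate 1 the adjusted p of that list was 0.137, with the deposited log2 values it was 0.0907, and under scaling over kept probes it was 0.0633. Of 12 Hox genes 6 rose and none fell, also adjusted over the list alone (median 0.51, or 0.38 with bounds, camera adjusted p = 0.0515). Hoxb4 rose (1.45 ± 0.19, above background on 1 of the 2 control arrays), Hoxc9 was at least 1.96-fold, Hoxb9 at least 1.62-fold and Hoxd9 at least 1.02-fold higher. The ectoderm and neural list had 3 genes higher and 3 lower of 9, also adjusted over the list alone. Its median was 0.18 (0.13 with bounds), its mean was -0.37, and camera, with an adjusted p of 0.893, pointed down. Besides Otx2, the microtubule regulator gene Stmn2 was at least 3.92-fold lower and Gbx2 fell (-2.19 ± 0.17), while the cadherin gene Cdh2 was at least 1.74-fold higher, with a second probe at -0.15.

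Cell cycle and nucleolar genes were lower in the Oct4 knockdown. Of 32 cell cycle genes 17 fell and 5 rose (19 and 5 adjusted over the list alone), with a median of -0.66 (camera adjusted p = 0.00195, and adjusted p = 0.411 with an estimated correlation). The mitotic kinase gene Aurka fell (-1.79 ± 0.17), and the inhibitor genes Cdkn2b (3.10 ± 0.20, above background on 1 of the 2 control arrays) and Cdkn1c (2.12 ± 0.25) and Ccnd2 (2.10 ± 0.15) rose. Of 22 nucleolus and ribosome biogenesis genes 13 fell and none rose (14 and 1 adjusted over the list alone), with a median of -0.54 (camera adjusted p = 0.000276, and adjusted p = 0.411 with an estimated correlation). Ncl, encoding nucleolin (-1.31 ± 0.18), Nop56 (-1.21 ± 0.15), Nop58 (-1.12 ± 0.24) and Gar1 (-1.07 ± 0.14) fell. Of 25 p53 targets 12 rose and 2 fell (13 and 2 adjusted over the list alone), with a median of 0.48 (camera adjusted p = 0.0228, and adjusted p = 0.411 with an estimated correlation). Plk2 (2.10 ± 0.16), the kinase inhibitor gene Cdkn1a (1.94 ± 0.16) and Mdm2 (1.36 ± 0.14) rose and the death receptor gene Fas was at least 1.56-fold higher. The p53 call ended under scaling to a common median (camera adjusted p = 0.0635) and without GFP replicate 2 (adjusted p = 0.131).

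The remaining lists had no call by camera in the Oct4 comparison. Of 19 glycolysis and hypoxia genes 8 rose and 4 fell (9 and 4 adjusted over the list alone), with a median of 0.39, or 0.27 with bounds (adjusted p = 0.204). Pfkp (-1.71 ± 0.14) and Pdk1 (-1.43 ± 0.14) fell, P4ha2 rose (1.64 ± 0.14) and Ndrg1 was at least 1.20-fold higher. Of 22 integrated stress response genes 8 fell and 3 rose (9 and 3 adjusted over the list alone), with a median of -0.25 (adjusted p = 0.162). The amino acid transporter gene Slc7a3 (-2.55 ± 0.22), Chac1 (-2.08 ± 0.14) and Nupr1 (-1.58 ± 0.15) fell and Atf3 was at least 4.76-fold higher. Of 9 interferon response genes 4 rose and 3 fell (5 and 3 adjusted over the list alone), with a median of 0.49, or 0.11 with bounds (adjusted p = 0.667). The class I antigen genes B2m (2.20 ± 0.14) and H2-D1 (1.42 ± 0.20) rose, and Ifitm1 (-1.70 ± 0.14) and Ifitm3 (-1.43 ± 0.14) fell. Of 6 germline genes 2 fell, also adjusted over the list alone, Syce1 (-1.35 ± 0.26) and Ddx4 (-0.63 ± 0.15, above background on 1 of the 2 knockdown arrays), with a median of -0.28 (adjusted p = 0.225). Of 5 Nodal and Wnt targets 3 rose and 2 fell, also adjusted over the list alone, with a median of 0.87 (adjusted p = 0.846, with fry pointing down). Id3 (1.38 ± 0.16) and Id1 (1.22 ± 0.15) rose, and Acvr2b (-1.58 ± 0.14) and Nodal (-1.34 ± 0.15) fell. No two-cell-like gene was measured.

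Under scaling to a common median the calls of Bmp4, Cdh2, H2-D1, Hoxb9, Id1, Id3, Mdm2, Ndrg1 and Rspo3 ended, and the medians of the ectoderm (-0.34), Hox (-0.01), p53 (-0.13) and glycolysis (-0.33) lists turned negative. Relative to the median of all genes under that scaling they were 0.19, 0.53, 0.41 and 0.21. That scaling moved 12 of the 32 counts of list members by over 1.5 times. It gave 3 p53 targets higher and 3 lower, 1 and 4 glycolysis genes, 1 and 11 COMPASS genes, 0 and 3 ectoderm genes, 0 and 2 Nodal and Wnt targets and 1 and 3 interferon response genes. For Hox genes the counts were 3 higher and 1 lower, for mesoderm 2 and 0, for trophectoderm 10 and 2 and for primitive endoderm 11 and 2. Leaving out Oct4 knockdown replicate 1 moved 18 of the 32 counts by over 1.5 times and replicate 2 moved 17. With either left out, fewer trophectoderm, fibroblast, p53, Hox and mesoderm genes were called higher. Part of this was fixed in advance, since genes detected only on the 2 knockdown arrays then failed the filter. In the full set 7 of 20 trophectoderm genes, 7 of 19 fibroblast markers and 3 of 5 mesoderm genes were not above background in 1 of the groups. Nucleolar genes lower were 1 without replicate 1 and 4 without replicate 2, and cell cycle genes lower 7 and 11. Pluripotency genes lower were 18 and 20, and primitive endoderm genes higher 10 and 10. Without either GFP array 1 ectoderm gene was lower, without GFP replicate 1 also 1 Hox gene, and without GFP replicate 2 there were 2 glycolysis genes lower. Without Oct4 knockdown replicate 1 the calls of Ash2l, Bmp4, Ddx4, Gar1, Id1, Kansl2, Ncl, Nop58, Rbbp5, Syce1 and Zfp42 ended, and without replicate 2 those of Ash2l, Bmp4, Cdh2, Ddx4, Kansl2 and Rbbp5. With no filter on dim probes the calls of Ash2l, Kansl2, Nop58, Rbbp5, Syce1 and Zfp42 ended (limma adjusted p from 0.061 to 0.12), the call of Ash2l also ended without GFP replicate 2 (limma adjusted p = 0.107), and that of Ddx4 with the deposited log2 values and with a trended variance model. Of the 1649 genes with several kept probes, 62 had probes called in opposite directions. Other probes were at 3.76 for Pmp22 and at -2.28 and -0.02 for Ifitm1.

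**Figure D2:**
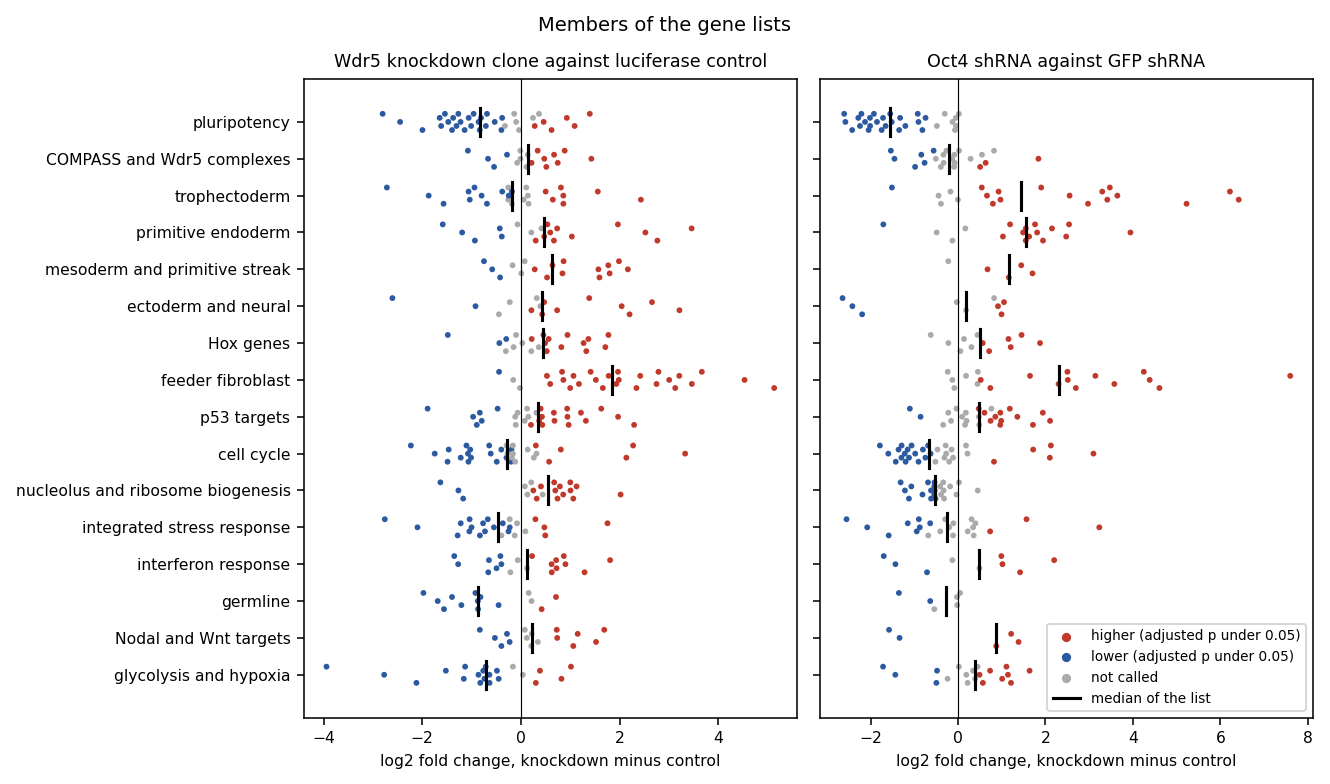
Log2 fold change, knockdown minus control, of the measured members of each gene list, with 1 point per gene, fitted values of genes below background in a group included, coloured by its call, and a black bar at the list median. The pluripotency medians lie at -0.82 and -1.55 and the fibroblast marker medians at 1.85 and 2.30.

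The knockdowns shared more calls than independent lists would. Pluripotency genes such as Sox2, Nanog, Esrrb and Zfp42 fell in both, and Col4a1, Ccnd2, Cdkn2b and Plk2 rose in both. Of the 6170 genes tested in both comparisons, 944 were higher in both, from 2474 calls in the Wdr5 and 1579 in the Oct4 knockdown, where 633 would be shared by independent lists (odds ratio 2.97, two-sided Fisher's exact test p = 2.6e-75). For lower genes, 622 were shared of 1961 and 1180 calls, against 375 (odds ratio 3.04, Fisher's exact test p = 1.7e-62). Opposite calls were fewer than for independent lists, with 250 genes higher in the Wdr5 and lower in the Oct4 knockdown against 473, and 270 the other way against 502. Log2 fold changes correlated across genes with a Pearson r of 0.39 and a Spearman rho of 0.358. Genes are not independent replicates, so these p-values describe the overlap of the lists and not its repeatability. Without Oct4 knockdown replicate 1 the shared counts were 221 higher and 174 lower, without replicate 2 they were 330 and 289, and under scaling to a common median 290 genes were higher in both.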

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

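The tests of the difference between the knockdowns reported here were chosen after the fold changes were seen. Of 105 named genes tested in both comparisons, 15 were called in opposite directions. Because these genes were picked for opposite calls, a test of the difference was bound to pass (adjusted p from 8.6e-06 to 0.000946) and adds nothing to the calls themselves. Platforms, probes and cell lines differ between the comparisons, so only the opposite signs are read and not the sizes.

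The genes lower in the Wdr5 and higher in the Oct4 knockdown had these fitted differences, Wdr5 minus Oct4, on the log2 scale. The value was -6.46 for the keratin gene Krt7, which fell by 0.25 in the Wdr5 knockdown. It was -6.01 for Rhox6, which was below background in the Wdr5 knockdown and in the GFP control, so that only bounds hold, at least 5.80-fold lower and at least 4.47-fold higher. For Rhox9 it was -5.51, with the GFP control below background and a bound of at least 9.30-fold higher in the Oct4 knockdown. The values for Ndrg1, Rspo3, Hoxd9 and Id1 were -2.73, -1.74, -1.45 and -1.44, and all but Id1 were below background in the GFP control, where the bounds on the rise were 1.20-fold, 1.26-fold and 1.02-fold. Genes higher in the Wdr5 and lower in the Oct4 knockdown included 3 nucleolar genes, Gar1 (1.80), Nop58 (1.98) and Ncl (2.44). The others were Gbx2 (2.40), Ifitm3 (2.72), Robo4 (5.19), Stmn2 (2.88) and Yme1l1 (3.56). Some of these differences rest on small changes in the Wdr5 knockdown. There Gbx2 was at 0.21 (limma adjusted p = 0.0386), Id1 at -0.23 (limma adjusted p = 0.0436) and Hoxd9 at -0.30 (limma adjusted p = 0.00832). The median over all genes of that comparison was 0.10, so the opposite signs of such genes are weakly held. Stmn2 and Yme1l1 were below background in the Oct4 knockdown, with falls of at least 3.92-fold and 5.14-fold. In all, 520 genes were called in opposite directions.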

How the results depend on the processing

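Scaling over kept probes, probes detected on every array and the crossed pairing were tests chosen only after the results were seen. The fall of Wdr5 ranged from -0.97 to -0.71 over the alternatives and from -1.01 to -0.92 with each array left out. The -0.71 is from the authors' deposited table, whose average log2 values, sorted, differ by up to 0.14 from the sorted means of the deposited log2 values for an unknown reason. The fall of Pou5f1 ranged from -2.93 to -1.70 and from -2.39 to -2.17. Both passed the threshold in each of these, except that Wdr5, at -0.96, misses a 2-fold minimum. That minimum left 1141 higher and 974 lower genes in the Wdr5 and 1131 and 682 in the Oct4 knockdown, with 257 higher and 140 lower in both, by its construction. Scaling to a common median gave 578 higher and 2765 lower genes in the Oct4 knockdown and 290 higher in both. Probes detected on every array gave 1279 higher genes in the Oct4 knockdown, where fewer genes were tested. In the Wdr5 knockdown 55.6% of the calls were higher, and scaling moved this split to 50.7% with a common median (3441 higher and 3347 lower) and 61.7% over kept probes (4417 and 2742). With each array left out, counts ranged from 3352 to 3692 higher and 2380 to 3001 lower genes in the Wdr5 knockdown. In the Oct4 knockdown they ranged from 387 to 2616 and from 418 to 1911, lowest without Oct4 knockdown replicate 1 (387 and 418), then replicate 2 (580 and 692). A lone array left in a group was then assumed to vary like the other group. Genes detected only on the 2 arrays of a group were no longer tested when 1 of these was left out. The genes shared by both knockdowns ranged from 221 to 1073 higher and 174 to 609 lower, and the correlation from 0.356 to 0.396. Klf4 turned to -0.66 in the Oct4 knockdown in the authors' deposited table and with the deposited log2 values, where another probe is brightest, and to -1.59 without Oct4 knockdown replicate 2 (highest 0.0224, without GFP replicate 2). Cdh2 turned to -0.31 without replicate 1 (highest 1.13, without GFP replicate 2). The brightest Cdh2 probe was below background on both GFP arrays, so without a knockdown array it failed the filter. Its other probe, at -0.15 in the full set, then stood for the gene. For Klf4 the 2 brightest probes had nearly the same mean log2 signal (8.999 and 8.965) and log2 fold changes of 0.02 and -1.28. Whether a change of probe made its turn with an array left out was not tested. Across the tested genes, the log2 fold changes of the authors' deposited table had a slope of 0.495 on those given here in the Wdr5 set (r = 0.881). In the Oct4 set the slope was 0.407 (r = 0.873), so the sizes of the folds depend on the processing. Many of the bounds given here were not reached in the authors' deposited table. In the Oct4 set Acta1 was at 3.84 there, Nts at 2.26, Gadd45g at 2.02, Pmp22 at 1.92, Timp3 at 1.89 and Rhox9 at 1.28. Among the falls Tera-pending was at -1.26, Yme1l1 at -0.74 and Otx2 at -0.58. All of these were smaller than their bounds, while Hoxd9, at 0.19, was above its bound.

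Named genes kept direction and side of the threshold in 1519 gene and setting pairs of the Wdr5 comparison and lost the call in 14, and in the Oct4 comparison in 1423 and 46. Camera with the preset correlation lost a list call in 9 list and setting pairs of the Wdr5 and 5 of the Oct4 comparison, and gained a call in 8 and 6. Fry, whose null is no change and not other genes, called a further 9 and 5 lists. All 7 list calls of the Wdr5 and all 8 of the Oct4 comparison were lost with an estimated correlation. That correlation was under the preset 0.01 for the fibroblast (0.00449), glycolysis (-0.0217) and germline (-0.04) lists of the Wdr5 comparison. For the primitive endoderm list of the Oct4 comparison it was -0.00399. A larger correlation thus does not account for those losses. For the pluripotency lists it was above 0.01, at 0.047 in the Wdr5 and 0.286 in the Oct4 comparison. Same-numbered arrays did not deviate together in the Wdr5 set (correlations of -0.03 and -0.01), and the numbers share nothing stated in the labels. With the replicate block, 3593 genes were higher and 2839 lower in the Wdr5 knockdown and 1967 and 1338 in the Oct4 knockdown. In the Oct4 set the correlation was -0.36, and the crossed pairing gave 2572 and 2147. The beadchip as a block and the deposited log2 values of the Wdr5 set by gene were not run. Over its probes without names those values gave 4712 higher and 4639 lower probes, against 4666 and 4615 here. Signal over background limits which genes can be measured, since at most 25.3% of probes were detected on an array of the Oct4 set and at most 51.0% in the Wdr5 set.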

Other observations

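The gene groups in this part, the single genes named from them and from the fibroblast list, and the tests of feeder RNA, of the loss of dim probes and of the trend subtracted from the Oct4 set were chosen only after their values were seen. Set tests of these groups were adjusted over these groups alone. Their adjusted p therefore cannot be set beside those of the lists fixed in advance, which were adjusted over more lists. In the Wdr5 knockdown, genes of ribosomal proteins and of mitochondrial complex I were lower, while 13 of 20 nucleolus and ribosome biogenesis genes were higher. Of 56 measured ribosomal protein genes 37 fell and 3 rose, with a median log2 fold change of -0.60 (camera adjusted p = 2.6e-07, and adjusted p = 0.0175 with an estimated correlation). Rps6 (-2.29 ± 0.06) and Rpl7a (-2.18 ± 0.09) had the largest falls, and Rpl41 rose (0.42 ± 0.07). These counts use the brightest probe, and some other probes disagreed. Rpl38 was at 0.33 and -1.74 and Rpl7l1 at -0.70 and 0.37, all called, the brightest probe first. Rps3 (-1.45 and -2.79), Rps9 (-0.87 and -1.44), Rpl31 (-0.75 and -1.18) and Rpl29 (-0.63 and -1.10) fell on both probes. The elongation factor gene Eef2 fell on each of its 3 probes, at -3.25, -3.26 and -3.42. Of 33 genes of mitochondrial complex I, 27 fell and 1 rose (median -0.66, camera adjusted p = 3e-08, and adjusted p = 0.0175 with an estimated correlation). In the Oct4 knockdown 12 of 53 ribosomal protein genes fell and 1 rose (median -0.22, camera adjusted p = 0.0207, and adjusted p = 0.371 with an estimated correlation), and 4 of 31 complex I genes fell (median -0.19, camera adjusted p = 0.0597, and adjusted p = 0.215 with an estimated correlation). Without Oct4 knockdown replicate 1 or replicate 2 the ribosomal protein genes that fell were 1 and 2, and no complex I gene was called. Whether these groups differ between the knockdowns was not tested.

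Genes of the contractile and actin cytoskeleton rose in both knockdowns, 19 of 23 in the Wdr5 set (median 1.37, camera adjusted p = 2e-05, and adjusted p = 0.0281 with an estimated correlation) and 18 of 22 in the Oct4 set (median 2.49, camera adjusted p = 7.7e-11, and adjusted p = 0.215 with an estimated correlation). Tpm1 was at 2.20 ± 0.07 and 4.47 ± 0.15, and Flna at 1.98 ± 0.07 and 2.57 ± 0.17, while Tpm3 fell by its brightest probe in both, at -1.12 ± 0.11 and -0.98 ± 0.16, with other probes in the Oct4 set at 0.68, -0.35 and 1.15. In the Wdr5 set 3 members fell, Tpm3, Myl2 and Myl4, and in the Oct4 set 1. The fibroblast markers rose on the same arrays (medians 1.85 and 2.30), and Acta2 and Tagln belong to both groups. Without these 2 genes 17 of 21 rose in the Wdr5 set (median 1.27) and 16 of 20 in the Oct4 set (median 2.40). Of 15 imprinted genes 10 rose and 1 fell in the Oct4 knockdown (median 1.00, or 0.65 with genes below background at their bound, camera adjusted p = 0.00646, and adjusted p = 0.215 with an estimated correlation). Besides Igf2, its neighbour H19 was at least 8.54-fold, Dlk1 at least 8.45-fold and Peg3 at least 3.91-fold higher, and Snrpn fell (-0.99 ± 0.15). In the Wdr5 knockdown 6 of 15 imprinted genes rose and 5 fell, with H19 at -1.72 ± 0.09 and Igf2 not called (0.16 ± 0.07). Of 9 Rhox and Xlr genes, X-linked and expressed in reproductive tissues, 6 fell and none rose in the Wdr5 knockdown (median -1.87, or -1.76 with bounds, camera adjusted p = 0.00186, and adjusted p = 0.0571 with an estimated correlation). All 4 measured in the Oct4 knockdown were called higher, a group under the minimum of 5 members, so no set test is read. Of these, 3 were below background on the GFP arrays and could pass the filter only through the knockdown arrays, so their direction adds no support. Of those 4, Rhox5 rose (1.03 ± 0.15), Rhox6 was at least 4.47-fold and Rhox9 at least 9.30-fold higher, and Rhox8, below background on the control arrays, has no bound above 1. In the Wdr5 set 3 of 5 measured Rhox and Xlr genes fell without luciferase replicate 1 (median -1.98) and 3 of 6 without replicate 2 (median -0.94). Without Oct4 knockdown replicate 1 or replicate 2 the contractile genes higher were 11 and 12 of 16 measured, the imprinted genes 3 and 4 of 11 (medians 0.47 and 0.68), and 1 Rhox gene was measured. The directions of these group medians were the same under each scaling and background alternative run.

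The rise of fibroblast markers in the Wdr5 knockdown could come from feeder RNA or from the ES cells. The scaling between arrays is argued against as the whole source, since the list median was 1.67 with arrays scaled to a common median. Feeder RNA cannot be told apart from a change in the ES cells: 25 of the 28 markers rose, but differentiating cells can raise the same genes, and Thy1 fell while Lgals1 and Mmp2 were not called. The collagen gene Col1a1 was at 3.21 ± 0.07, Col3a1, above background on 1 of the 2 control arrays, at 2.75 ± 0.13 and Vim at 1.00 ± 0.07. The clone and doxycycline, which differ with the knockdown, stay open and untested.

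The fall of ribosomal protein genes in the Wdr5 knockdown may be a change in the cells. Compression of very bright probes pulls changes towards 0. What it does to the difference between the groups after quantile normalization was not tested, so it is not excluded. An effect common to bright probes is argued against, since random lists of other genes matched on signal had a median of 0.139 and the lowest of 10000 was at -0.20 (0.01% as low, the smallest share they can give). Of the 56 members, 32 lay in the brightest of 50 signal classes, beside 171 other genes, and signal was not matched within it. An effect confined to the very brightest probes was therefore not tested. With arrays scaled to a common median the ribosomal protein genes were at -0.65, which argues against the quantile normalization as the source. Probes shared between ribosomal protein genes and their pseudogenes, the clone and doxycycline stay open and untested.

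The Oct4 knockdown arrays were dimmer, which might have created changes in dim genes. A net loss of dim probes on these arrays is argued against. Genes above background on the Oct4 knockdown arrays only were 3.52 times as many as those on the GFP arrays only (940 against 267). That excess cannot clear a technical effect on dim genes, since detection differed between the arrays. The lowest log2 signal among detected probes was 6.39 and 6.67 on the GFP arrays and 6.44 and 6.22 on the Oct4 knockdown arrays. Detected probes numbered 10661 and 9020 against 10331 and 11804. A trend of the fold change with signal left by the normalization is argued against as the source of the calls as a whole, since 85.9% of the 3930 called genes were still called the same way after a smooth trend was subtracted, with 963 higher and 674 lower by at least 2-fold. The subtracted trend ran from -0.11 to 1.3 on the log2 scale, so in part of the signal range it was over 2-fold. For the excess of higher calls (57.3% of the calls, and 55.4% after the subtraction) such a trend cannot be told apart from real changes, since the medians over 5 classes of mean signal spanned 0.209, between the bounds set in advance, and the dimmest class had 637 genes higher and 165 lower against 348 and 408 in the brightest. The knockdown itself stays open as the source, and the cause of the lower intensities was not tested.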
